A study of Arabidopsis thaliana and Cuscuta campestris with 12 samples.

How the data were processed

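Small RNA sequencing was carried out on 4 groups of 3 libraries: unpurified RNA (Input) and RNA purified with TraPR from Arabidopsis thaliana stems next to the attachment sites of the parasite Cuscuta campestris, and Input and TraPR RNA from C. campestris haustoria grown in vitro. Per the series' design text, each biological replicate of stems pooled 30 to 40 segments of 2 to 3 mm (80 mg) from hosts infected for 10 days, and each replicate of haustoria used 60 to 70 seedlings (50 mg of tissue). Per the labels, libraries were read single-end at 50 nt after selection of 145 to 195 bp products. Replicate numbers (RepID) 1 to 3 are stems and 4 to 6 are haustoria.

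The authors deposited 6 tables, 1 per RepID, each with the same 52573 features: 268 microRNA sequences and 52305 siRNA loci of C. campestris. The 2 measured columns are, per the file headers, a log2 ratio and a log10 abundance. From the values, the deposited log2 ratio is that of RPM (reads scaled to a fixed library total) in a pair of libraries, absent where both are under 2 RPM, and the deposited log10 abundance is that of 1 plus the mean RPM of the pair. The headers do not say which library is the numerator of the ratio. It was read as TraPR over Input, because each table is recorded under its TraPR sample, and every direction below rests on that reading. The aligner, the counting, the annotation and the rule by which the authors assigned features to categories are not given in the sources used here. The submitters' processing notes name the build TAIR10 for Arabidopsis, and loci of C. campestris carry the chromosome names of an assembly whose build is not given in the sources used here.

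Solving both columns together gave whole reads in both libraries for 100% of the features of each table, and the total reads of each library. On simulated columns of 20000 features in 3 pairs of libraries the same procedure returned the totals of 3 pairs and 100% of the reads. These recovered reads, divided by library totals, are the RPM used here. Library totals were 2679508, 4339289 and 3888703 reads in stem Input, 10091554, 5416072 and 8480298 in stem TraPR, 7586447, 7759694 and 4148416 in haustoria Input, and 119406542, 21756949 and 11920010 in haustoria TraPR, each in order of RepID. A library's read was therefore worth between 0.00837 and 0.373 RPM. Replicates within a group differed by more than counting noise (chi-square per feature of at least 14.5), so the spread between libraries sets the error. Over features above a minimum of reads, log2 levels of haustoria Input replicates correlated at only 0.234 to 0.271, against 0.763 to 0.875 in haustoria TraPR. In stems the correlations were 0.713 to 0.757 in Input and 0.477 to 0.539 in TraPR. The 3605 features called in haustoria by the fit below became 2873 to 4264 without 1 Input library. They became 926 to 2005 without 1 TraPR library.

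Features with a mean of at least 1 RPM over the libraries compared were tested with limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with a trend in the prior variance, library totals as the scaling, no replicate block and a Benjamini-Hochberg adjusted p of 0.05 as the threshold. The unit differed from the counts that the plan put first, and the plan's test for normalized values was used. Fold changes are on the log2(RPM + 1) scale, which understates changes of low features. The 5 comparisons were TraPR against Input in stems, the same in haustoria, the difference between these effects (features with a mean of at least 1 RPM in the libraries of each tissue), and haustoria against stems within TraPR and within Input libraries. On reads simulated from the mean levels of the real features with a dispersion of 0.15, where 50 features with a mean of at least 5 RPM were changed by each size, the stem fit tested 2468 features. It recovered 24% of those changed by a log2 of 1, 86% of those changed by 2 and 100% of those changed by 3. The haustoria fit tested 51716 features and recovered 4%, 60% and 100%. False calls were 4.91% and 4.35% of the calls. The simulated features varied independently with this 1 dispersion. In the real stem libraries the interface-induced class had an estimated correlation between members of 0.42, and some features spread more widely. These shares therefore may not hold for the real fits.

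Fixed lists of at least 3 tested members were compared with other features by camera, with a preset correlation of 0.01 and with an estimated one, and tested alone by fry. Shares of reads were compared by exact two-sided permutation tests of 3 against 3 libraries, whose smallest p is 0.10. Confidence intervals of reads are exact binomial at 95% and cover counting error only. A fold against a group with no reads is given as a lower bound, against 3 reads over the whole group. Sequences of microRNAs were matched exactly to the Arabidopsis assembly TAIR10.1 to give coordinates, and no coordinate was converted.

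Features named in the text follow a rule written before the data were examined. For each comparison it takes the 10 largest changes in each direction (5 for the tissue differences) among features past the threshold with a mean of at least 10 RPM and no overlap between groups, the members of the fixed lists with the highest means, and the 5 features with the highest mean in each group. For the difference between tissues, overlap was judged on the ratios of each RepID. Names chosen after their values were seen are marked as such. Some lists of the plan had no member among the features: trans-acting siRNA loci, host mRNAs with secondary siRNAs, structural RNAs and organelle RNAs.

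Alternatives fixed in advance were TMM and median-ratio scaling, voom on the recovered reads, no filter, a mean of at least 10 RPM, pseudocounts of 0.1 and 5, the RepID as a block, all 4 groups in 1 fit, and each library left out. Leaving out both libraries of a RepID, another filter for the difference between tissues, a test of the deposited log2 ratios against 0, thinning to equal depth and shares without the most abundant sequence or locus were added after the data were seen. The most abundant is that with the highest sum of mean RPM in Input and TraPR of the tissue, within the class whose reads are divided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.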

Results

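Small RNAs were sequenced from Arabidopsis stems beside attached Cuscuta campestris, a parasitic plant, and from haustoria, its feeding organs, induced in vitro without a host. TraPR, an ion-exchange purification of ARGONAUTE complexes with their small RNAs, was compared with unpurified Input RNA in each tissue, with 3 libraries in each of 4 groups. Library totals ranged from 2679508 to 119406542 reads. The files list 73 canonical microRNAs of the host, 59 canonical microRNAs of host and/or parasite, 136 interface-induced microRNAs of the parasite, and 242, 1701 and 50362 parasite siRNA loci of 21, 22 and 24 nt. These categories are the authors'. Directions rest on reading the deposited ratio as TraPR over Input, which the file headers do not state.

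The share of reads in each class asks what the purification retained. In stems, canonical host microRNAs were 0.809% ± 0.122 of Input reads and 4.51% ± 0.583 of TraPR reads (SD, n = 3), a ratio of 5.59. Much of it came from miR158a-3p, 49.5% of the class in Input and 75.3% in TraPR, and without it the ratio was 2.81. Canonical microRNAs of host and/or parasite were 2.96% ± 0.555 of Input and 6.58% ± 1.84 of TraPR reads. Without ccm-miR172ad;ath-miR172cd, 52.9% of this class in TraPR, they were 2.31% ± 0.407 and 3.10% ± 0.706, and the libraries overlapped (exact permutation p = 0.30). Counted as distinct sequences, both canonical classes in stems were lower shares of all listed features with at least 1 RPM in TraPR. That total includes the siRNA loci, so such a share can fall without fewer canonical sequences. Interface-induced microRNAs were 1.04% ± 0.526 of Input and 0.728% ± 0.0973 of TraPR reads in stems, a difference within the spread of the Input libraries (exact permutation p = 0.40). In haustoria the same class was 2.03% ± 0.553 of Input and 0.0747% ± 0.0137 of TraPR reads, 26.8-fold lower. Parasite 24-nt siRNA loci took 31.7% ± 1.14 of haustoria Input and 27.6% ± 1.55 of TraPR reads. Loci of 21 nt took 0.597% ± 0.00299 and 1.06% ± 0.328 of the same libraries, and loci of 22 nt 3.77% ± 0.101 and 4.97% ± 0.765. Cluster_27171 made up 35.2% of the 21-nt class in TraPR, and without it the ratio fell from 1.73 to 1.44. The median log2 fold change of the 240 tested loci of 21 nt was -0.21 (0.24 with TMM scaling). For the stem canonical classes and for the haustoria classes named here, the Input and TraPR libraries did not overlap, and the exact two-sided permutation p was 0.10, the smallest that 3 against 3 libraries allow.

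**Figure D1:**
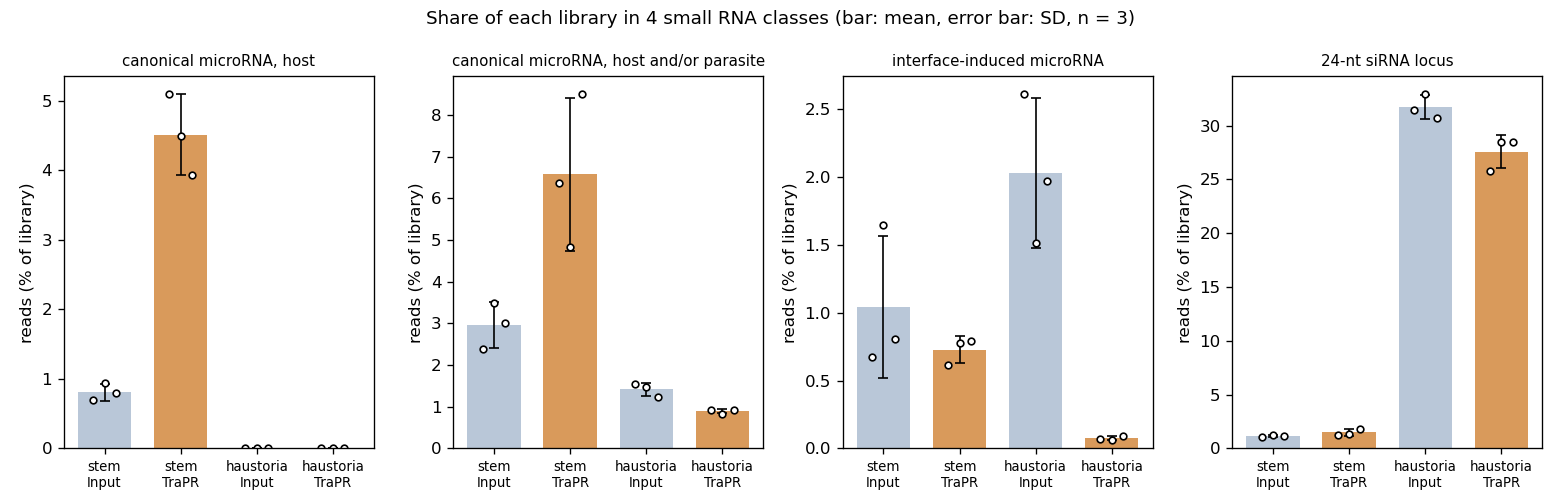
Share of reads (% of the library, y axis) in 4 small RNA classes for the 4 groups of libraries. Bars are means, error bars SD and points the 3 libraries. The interface-induced class has a mean of 2.03% in haustoria Input and 0.0747% in haustoria TraPR, without overlap.

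Sizes are those of the listed features alone, which held 6.03% ± 1.28 of stem Input and 13.5% ± 1.87 of stem TraPR reads. In haustoria they held 39.5% ± 1.19 and 34.6% ± 0.536, so these are not size profiles of whole libraries. By size, 20-nt features made up 0.513% ± 0.0384 of stem Input and 3.69% ± 0.637 of stem TraPR reads, and 0.235% ± 0.0185 and 0.0197% ± 0.00381 of the same haustoria libraries (SD, n = 3). Features of 21 nt made up 3.45% ± 0.727 and 6.89% ± 1.87 in stems and 2.78% ± 0.323 and 1.95% ± 0.340 in haustoria. Features of 23 nt were 38.4-fold lower in haustoria TraPR than Input and 2.88-fold lower in stems. Each of these differences had an exact permutation p of 0.10. The stem values rest largely on 1 sequence each. Counted as distinct features, those of 20 and 21 nt were lower shares of all listed features with at least 1 RPM in TraPR. Of reads on listed 20-nt features in stem TraPR, 92.2% were miR158a-3p, without which the ratio fell from 7.12 to 2.62. Without ccm-miR172ad;ath-miR172cd the ratio of 21-nt features in stems fell from 1.98 to 1.22 (exact permutation p = 0.40), and without their most abundant sequence 23-nt features were 1.69-fold lower (exact permutation p = 0.30). In haustoria, 90.6% of TraPR reads on listed 20-nt features were ccm-miR156dgijkl;ath-miR156abcdef. Among the 22-nt microRNAs, sequences with a 5' U held 69.7% ± 2.15 of Input and 97.8% ± 1.87 of TraPR reads in stems, and 75.5% ± 3.08 and 94.5% ± 2.54 in haustoria. Among the 21-nt microRNAs, 5' C held 3.29% ± 0.0867 and 0.311% ± 0.0602 in stems and 10.1% ± 1.48 and 1.01% ± 0.161 in haustoria. The share of 5' A was 27.9% ± 1.26 in Input and 57.0% ± 8.03 in TraPR in stems, but 11.1% ± 1.03 and 14.6% ± 5.06 without ccm-miR172ad;ath-miR172cd. It was 10.1% ± 1.81 and 5.61% ± 0.609 in haustoria, but 10.5% ± 1.76 and 10.7% ± 2.64 without ccm-miR159ab;ath-miR159a. The share of 5' U was 64.7% ± 1.24 and 39.8% ± 8.15 in stems, where its reads were not fewer in TraPR (22184 ± 4304 and 26567 ± 5080 RPM), and 79.8% ± 1.09 and 79.0% ± 6.04 without ccm-miR172ad;ath-miR172cd. In haustoria 5' U held 67.7% ± 5.95 and 92.8% ± 0.714, and 66.2% ± 5.86 and 86.3% ± 2.89 without ccm-miR159ab;ath-miR159a (exact permutation p = 0.10 in each). Within the interface-induced class, 5' U held 53.5% ± 3.79 of Input and 82.8% ± 6.26 of TraPR reads in stems and 59.7% ± 4.39 and 79.6% ± 3.62 in haustoria, without overlap between libraries (exact permutation p = 0.10 in each). The first base of a small RNA is known to guide its sorting among ARGONAUTE proteins.

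**Figure D2:**
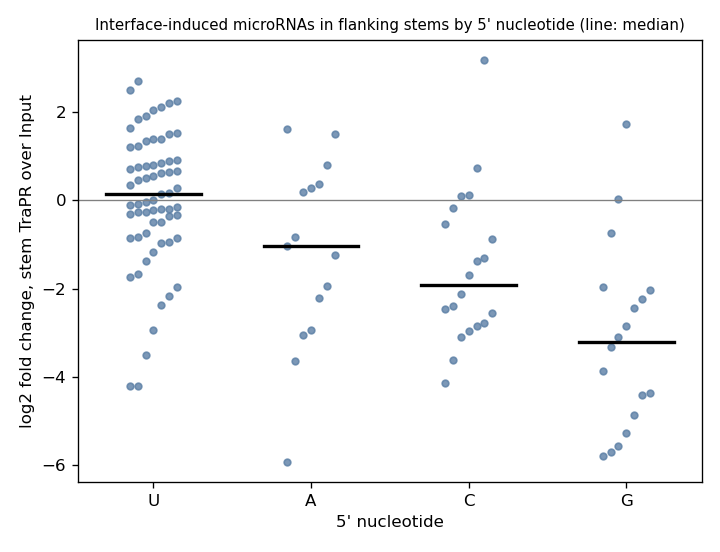
Log2 fold change of TraPR over Input in stems (y axis) for the 118 interface-induced microRNAs tested, by 5' nucleotide (x axis). Points are sequences and lines medians, which run from 0.14 for U to -3.22 for G.

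The comparison of TraPR with Input in stems asks which small RNAs of the infected host stem are carried by ARGONAUTE complexes. The Brassicaceae microRNA miR158a-3p, the most abundant host microRNA, rose from 4005 ± 165 to 33983 ± 6309 RPM (SD, n = 3). Its relative miR158b rose from 4.15 ± 2.67 to 99.2 ± 20.1 RPM. The trigger of secondary siRNAs at disease resistance genes, miR472-3p, rose from 109 ± 28.9 to 1788 ± 503 RPM, and miR393ab, which targets auxin receptor mRNAs, from 42.3 ± 28.5 to 681 ± 171 RPM. On TAIR10.1, miR158a-3p lies on chromosome 3 (3366349 to 3366368), miR472-3p on chromosome 1 (4182143 to 4182164), and miR393ab at 2 places, on chromosomes 2 and 3. Many interface-induced parasite microRNAs fell: ccm-IIM-20 from 102 ± 81.4 to 0.561 ± 0.328 RPM, ccm-miR12485 from 126 ± 74.7 to 2.18 ± 3.43 RPM and ccm-IIM-94 from 199 ± 30.0 to 5.33 ± 6.54 RPM.

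Of 2279 features tested in stems, limma called 127, of which 82 rose and 45 fell. Of 42 host canonical microRNAs, 15 rose, 3 fell and 24 did not pass, with a median log2 fold change of 0.90. The 3 that fell, named after their values were seen, were miR395ade (-2.95), miR395bcf (-2.80), both targeting sulfate assimilation, and miR824-5p (-2.79), a regulator of stomatal development. Their calls were lost without the TraPR library of RepID 1 (adjusted p of 0.180, 0.140 and 0.132) or of RepID 2 (0.123, 0.123 and 0.153). Of 23 Brassicaceae microRNAs, 11 rose and 1 fell, and 15 passed adjusted over the list alone. The list lay above other features by camera (adjusted p = 6.96e-09), and adjusted p = 0.187 with an estimated correlation. Of 10 triggers of secondary siRNAs, 5 rose and 0 fell, with 8 adjusted over the list alone (camera adjusted p = 3.66e-07, and adjusted p = 0.191 with an estimated correlation). They include miR161.2, which rose by a log2 of 2.69 ± 0.49 (SE).

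Of 34 members of conserved developmental families in stems, 5 rose, 2 fell and 20 passed adjusted over the list alone. Their median was -0.06 (0.29 with TMM scaling, where 10 rose and 2 fell) and their mean 0.17, and camera gave adjusted p = 0.421. Among them ccm-miR172ad;ath-miR172cd, a regulator of flowering shared by both species, rose from 6500 ± 1481 to 34800 ± 12284 RPM, and miR167d, which targets auxin response factors, from 564 ± 101 to 3729 ± 1016 RPM. The most abundant miR166 sequence, ccm-miR166ai;ath-miR166abcdefg, had 4375 ± 1009 and 2432 ± 548 RPM (log2 -0.84, adjusted p = 0.133 in limma), and passed with median-ratio scaling (0.0284). It belongs to the 4 tested microRNAs that the plan listed under ARGONAUTE proteins other than AGO1, a sorting not tested here. Of these, 0 passed and 2 passed adjusted over the list alone (camera adjusted p = 0.0253, adjusted p = 0.426 with an estimated correlation, and 0.165 with TMM scaling). Of 13 nutrient and copper microRNAs, 2 rose and 2 fell, and 5 passed adjusted over the list alone (camera adjusted p = 0.596). Here miR398bc, which targets copper superoxide dismutases, rose by a log2 of 2.04, a call lost without the TraPR library of RepID 2 (adjusted p = 0.0940 in limma). Of 3 microRNAs that target the silencing machinery, 0 passed and 1 passed adjusted over the list alone (camera adjusted p = 0.370). One of them, miR162ab, which targets DCL1, had 412 ± 103 and 517 ± 26.9 RPM.

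Of 118 interface-induced microRNAs tested in stems, 8 rose, 33 fell and 77 did not pass, with a median log2 fold change of -0.42 (-0.69 with the 4 members at 0 in TraPR at their bound). The class median per RepID was -0.53 ± 0.94 (SD, n = 3), so its direction was not shown: without the Input library of RepID 2 it was 0.10, and with TMM scaling -0.03. Without the TraPR library of RepID 1, 13 members fell and 0 rose, and without that of RepID 2, 15 fell and 0 rose. The abundant member ccm-miR12492a fell from 650 ± 70.4 to 54.8 ± 62.5 RPM. On the log2(RPM + 1) scale the largest fall was that of ccm-miR12487b (log2 -5.94), whose call was lost without the TraPR library of RepID 2 (adjusted p = 0.0628 in limma). On leaving out libraries it ranged from -8.35 to -4.02, and ccm-IIM-20 from -6.32 to -5.19, so their order was not settled. The abundant ccm-miR12497f had 618 ± 262 and 299 ± 37.3 RPM and did not pass. Among those that rose was ccm-miR12491a, named after its values were seen, with a log2 of 2.27, whose call was lost without the TraPR library of RepID 1 (adjusted p = 0.169 in limma) or RepID 2 (0.109). The list of 141 microRNAs with a parasite name gave 9 up and 35 down, with 62 adjusted over the list alone. It holds sequences shared with the host (15 of the 33 such canonical microRNAs in the files match TAIR10.1 exactly), whose reads in stems cannot be assigned to a species. Camera placed the interface-induced class below other features (adjusted p = 4.67e-14), and adjusted p = 0.426 with an estimated correlation. The list with parasite names lay below other features too (camera adjusted p = 2.23e-12, and adjusted p = 0.426 with an estimated correlation). As 118 of its 141 members are the interface-induced class, this is not a separate result.

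Parasite siRNA loci were low in stems. Of 1910 loci of 24 nt, 44 rose and 7 fell (37 passed adjusted over the list alone), and of 168 loci of 21 or 22 nt, 10 rose and 0 fell (10 adjusted over the list alone). The shorter loci lay above other features by camera (adjusted p = 1.74e-04, and adjusted p = 0.627 with an estimated correlation), and the 24-nt loci were not shown to differ from other features (adjusted p = 0.882). The largest rise was at Cluster_59910 on parasite chromosome 26 (10441817 to 10442359), from 0.0768 ± 0.133 to 83.7 ± 34.9 RPM, followed by Cluster_12382 on chromosome 5 (6974545 to 6975098), from 0.124 ± 0.215 to 109 ± 105 RPM. The median of all stem features was 0.34, and 0.54 with TMM scaling, which called 156 features (117 up and 39 down). The majority that rose turned with voom (35 up and 44 down) and without the Input library of RepID 1 (44 up and 49 down). The count of 127 was 37 without the TraPR library of RepID 1, 39 without that of RepID 2, and 8, 45 and 82 without both libraries of RepID 1, 2 or 3. Without both libraries of RepID 1 the calls of miR158b (adjusted p of 0.188 in limma), miR393ab (0.0903), miR161.2 (0.395), ccm-IIM-94 (0.127), ccm-miR12485 (0.0836), ccm-miR12492a (0.218), Cluster_12382 (0.0696), ccm-miR12487b (0.423), ccm-miR12491a (0.460), miR395ade (0.423), miR395bcf and miR824-5p (0.395 each) and miR398bc (0.243) were lost. Those of ccm-miR12487b (0.228), miR395ade and miR395bcf (0.135 each), miR824-5p (0.246) and miR398bc (0.0649) were also lost without both libraries of RepID 2, and that of miR398bc without those of RepID 3 (0.133). With no filter, which tested 44437 features, 21 passed, and the calls of Cluster_59910, Cluster_12382, miR158b, ccm-IIM-20, ccm-IIM-94, ccm-miR12485, ccm-miR12491a, miR395ade, miR395bcf and miR824-5p (adjusted p of 0.578 for each in limma) and of ccm-miR12487b (0.236) were lost. A limma test of the deposited ratios against 0 called 122 of 415 stem features (93 up and 29 down). It lost the calls of ccm-miR172ad;ath-miR172cd (log2 2.38, adjusted p = 0.0535), ccm-miR12491a (0.0532), miR398bc (0.0721), ccm-miR12487b (0.0860) and miR824-5p (0.0989).

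The comparison of TraPR with Input in haustoria asks the same of the parasite's organ alone. Nearly the whole interface-induced class fell: of 84 members tested, 79 fell, 0 rose and 5 did not pass, with a median log2 fold change of -5.26 and RepID medians of -5.25 ± 0.54 (SD, n = 3). The median was -6.35 with the 5 members at 0 in TraPR at their bound. The abundant members ccm-IIM-100, ccm-IIM-76a and ccm-IIM-27 fell from 1655 ± 407 to 17.8 ± 5.12, from 1562 ± 512 to 52.5 ± 23.5 and from 1053 ± 229 to 22.4 ± 4.26 RPM. On the log2(RPM + 1) scale the largest falls were those of ccm-miR12478a, from 452 ± 171 to 0.758 ± 0.151 RPM, and ccm-miR12469a, from 479 ± 209 to 1.75 ± 1.61 RPM. That scale understates falls to near 0, so the order may differ on others. ccm-IIM-79a (log2 -7.34) and ccm-miR12465c (log2 -2.38) mark a wide range within the class. Camera placed the class below other features (adjusted p = 4.54e-86, and an adjusted p just under 0.05 with an estimated correlation).

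Of 30 canonical microRNAs of host and/or parasite in haustoria, 4 rose, 11 fell and 15 did not pass, with a median of -0.71 (-0.11 with TMM scaling; camera adjusted p = 0.0210, adjusted p = 0.379 with an estimated correlation, and 0.0987 with TMM scaling). The regulator of MYB factors ccm-miR159ab;ath-miR159a rose from 964 ± 297 to 4092 ± 531 RPM. The other 3 that rose, of which the first was named after its values were seen, were ccm-miR160abcd;ath-miR160abc (log2 1.77), ccm-miR168cd (0.75), whose family targets AGO1, and ccm-miR398ab (2.74). Without the TraPR library of RepID 4 or RepID 6 the calls of miR168cd (adjusted p of 0.0893 and 0.0796) and miR398ab (0.129 and 0.0947) were lost, and that of miR168cd also without the Input library of RepID 5 (0.0683) or with all 4 groups in 1 fit (0.384). Without both libraries of RepID 5 or 6 the call of miR160abcd was lost (adjusted p of 0.0576 and 0.0723 in limma). That of miR398ab was lost with voom (0.113), and both it and that of miR168cd were lost without both libraries of RepID 4, 5 or 6 (adjusted p from 0.0597 to 0.138). Of 26 members of developmental families, 2 rose and 11 fell, with 18 adjusted over the list alone (camera adjusted p = 2.60e-04, and adjusted p = 0.197 with an estimated correlation). The phase-change regulator ccm-miR156dgijkl;ath-miR156abcdef fell from 2085 ± 144 to 179 ± 27.6 RPM, and ccm-miR166bcdf from 3787 ± 634 to 467 ± 154 RPM. The second miR166 sequence, ccm-miR166ai;ath-miR166abcdefg, fell from 2616 ± 272 to 1345 ± 296 RPM, a call lost with TMM scaling (adjusted p = 0.496 in limma), median-ratio scaling (0.545) and all 4 groups in 1 fit (0.0768). Of 6 microRNAs that the plan listed under other ARGONAUTE proteins, 3 fell and 0 rose, with 5 adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.197 with an estimated correlation, and 0.0747 with TMM scaling). The AGO7 partner ccm-miR390ab;ath-miR390ab had 214 ± 32.6 and 317 ± 25.7 RPM and did not pass (adjusted p = 0.0572 in limma), but passed with TMM scaling (0.0233).

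Of 49987 siRNA loci of 24 nt in haustoria, 1797 rose, 1502 fell and 46688 did not pass, with a median of -0.55 (-0.11 with TMM scaling, where 3525 rose and 556 fell). They make up nearly all features and had no list test. Of 1910 loci of 21 or 22 nt, 181 rose and 31 fell, with 262 adjusted over the list alone. Their median was -0.04 (0.43 with TMM scaling, where 327 rose and 7 fell) and their mean 0.10, above other features by camera (adjusted p = 6.33e-08, and adjusted p = 0.115 with an estimated correlation). Among the largest rises were those at Cluster_33748 on parasite chromosome 14 (625191 to 625634), from 5.32 ± 1.18 to 151 ± 52.9 RPM, Cluster_34825 on the same chromosome (log2 4.40) and Cluster_67660 on chromosome 31 (log2 4.28). The 24-nt locus Cluster_56252 rose from 17.5 ± 8.95 to 214 ± 107 RPM. The abundant 21-nt loci Cluster_27171 on chromosome 11 and Cluster_22165 on chromosome 9 rose from 1260 ± 45.5 to 3749 ± 1605 and from 649 ± 91.6 to 2049 ± 837 RPM, calls lost with all 4 groups in 1 fit (adjusted p of 0.180 and 0.200 in limma). Cluster_26744 had 1688 ± 71.8 and 1858 ± 90.1 RPM and did not pass. The 111 microRNAs with a parasite name, 84 of them interface-induced, gave 4 up and 90 down, with 102 adjusted over the list alone (camera adjusted p = 2.08e-64, and an adjusted p just under 0.05 with an estimated correlation).

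Of 52011 features in haustoria, limma called 3605, of which 1982 rose and 1623 fell. The median of all features was -0.53, and -0.10 with TMM scaling, which called 3858 up and 647 down. The majority that rose turned with voom (2240 up and 9052 down), with all 4 groups in 1 fit (3094 up and 8926 down) and without the Input library of RepID 6 (2096 up and 2168 down). The count was 926, 1339 and 2005 without the TraPR library of RepID 4, 5 or 6, and 503, 612 and 1633 without both libraries of the same RepIDs. A limma test of the deposited ratios against 0 called 0 of 37764 features, 10091 of them at an unadjusted p under 0.05.

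The difference between tissues asks whether the purification treated the same small RNA differently in stems and haustoria. Of 74 interface-induced microRNAs tested, 62 were lower in haustoria than in stems in their TraPR to Input ratio, 1 was higher and 11 did not pass, with a median log2 difference of -5.08. ccm-IIM-100 had 16.6 ± 8.44 RPM in stem Input and 71.5 ± 11.7 in stem TraPR, against 1655 ± 407 and 17.8 ± 5.12 in haustoria (difference -8.60). ccm-miR12464a (-8.12), ccm-miR12465a (-7.85), ccm-IIM-27 (-7.21) and ccm-miR12496 (-3.65) were lower in the same sense. The 1 higher member was ccm-miR12487b (6.25), a call lost with a pseudocount of 0.1 (adjusted p = 0.126 in limma), with voom (0.531), with no filter (0.0994), with the filter over all 12 libraries (0.0960) and without both libraries of RepID 1 (0.0851) or RepID 2 (0.126, difference 4.33). The shared ccm-miR172ad;ath-miR172cd was lower in haustoria (-3.93), where it had 432 ± 58.0 and 157 ± 70.5 RPM. Cluster_67660 (5.48) and Cluster_14079 (4.47) were higher, and the call of Cluster_14079 was lost with TMM scaling (adjusted p = 0.111 in limma), median-ratio scaling (0.247), voom (0.0861) and a pseudocount of 0.1 (0.249).

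In all, 161 of 2173 features differed between tissues, 47 higher and 114 lower in haustoria. With TMM scaling 93 differed, 5 higher and 88 lower, and with a pseudocount of 0.1, 3 were higher and 102 lower. With a pseudocount of 5 the balance turned, with 283 higher and 156 lower, so the higher calls depend on the scaling and the pseudocount. Without the TraPR library of RepID 4, 106 differed, 14 higher and 92 lower, so the higher calls also depend on that library. Camera placed the interface-induced class below other features (adjusted p = 1.45e-80, and adjusted p = 0.00628 with an estimated correlation). For 95 microRNAs with a parasite name, 2 higher, 69 lower and 79 adjusted over the list alone, these values were 1.31e-62 and adjusted p = 0.00981 with an estimated correlation. Of these 95, 74 are the interface-induced class, so this is not a separate result. Of 1908 loci of 24 nt, 38 were higher, 37 lower and 57 passed adjusted over the list alone, above other features by camera (adjusted p = 4.93e-16, and adjusted p = 2.04e-04 with an estimated correlation), with a median of -0.04 and a mean of -0.06. The other features include the interface-induced class, with a mean of -4.52. Tested alone by fry, the 24-nt loci gave adjusted p = 0.660, so no shift of their own was shown. With TMM scaling 3 of them were higher and 33 lower. Of 20 developmental members, 1 was higher, 7 lower and 9 passed adjusted over the list alone (camera adjusted p = 0.0447, and adjusted p = 0.791 with an estimated correlation). Of 168 loci of 21 or 22 nt, 7 were higher, 8 lower and 15 passed adjusted over the list alone (camera adjusted p = 0.467). With TMM scaling 1 of these was higher, 2 were lower and 1 passed adjusted over the list alone. Of 4 microRNAs that the plan listed under other ARGONAUTE proteins, 1 was higher, 1 lower and 2 passed adjusted over the list alone (camera adjusted p = 0.640).

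**Figure D3:**
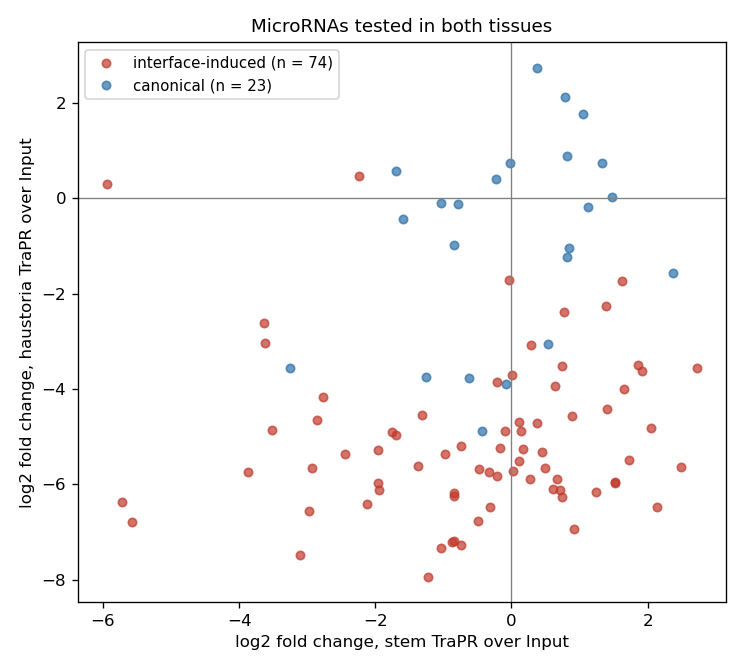
Log2 fold change of TraPR over Input in stems (x axis) and haustoria (y axis) for the 74 interface-induced and 23 canonical microRNAs tested in both tissues, each a point. The interface-induced sequences spread to both sides of 0 in stems, and nearly all lie below 0 in haustoria.

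Reads of each species in the other's tissue were compared next. Interface-induced parasite microRNAs reached 10437 ± 5260 RPM in stem Input and 7279 ± 973 RPM in stem TraPR (SD, n = 3), against 20337 ± 5528 and 747 ± 137 RPM in haustoria. Stem Input thus held 51.3% of the haustoria Input level in summed reads (exact permutation p = 0.20). Parasite siRNA loci in stem Input held 3.37% of theirs (exact permutation p = 0.10). With the deposited ratio read the other way, these levels were 974% and 4.88%. The 51.3% includes sequences that were lower in haustoria. For the 75 with at least 10 RPM in haustoria Input, the sums in stem Input were 16.3%, 41.7% and 19.4% of that level, in order of RepID. For siRNA loci chosen alike they were 2.25%, 2.92% and 2.83%. The host's own microRNAs reached 8092 ± 1217 RPM in stem Input and 0.0804 ± 0.139 RPM in haustoria Input, and 45140 ± 5834 and 0.939 ± 1.51 RPM in TraPR libraries. None of the 136 interface-induced sequences had an exact match in TAIR10.1.

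Within TraPR libraries, 32986 of 34749 features differed between tissues in limma, 32820 higher and 166 lower in haustoria, and within Input libraries 42114 of 50788, 42014 higher and 100 lower. Tissue, species and growth conditions differ together here. Host microRNAs were lower in haustoria: miR158a-3p had 33983 ± 6309 RPM in stem and 0.534 ± 0.847 in haustoria TraPR, and miR394ab 2603 ± 304 and 0.00279 ± 0.00484. In Input libraries miR159b-3p, which the authors list under host and/or parasite, had 1913 ± 344 and 2.46 ± 2.08 RPM. Parasite features were higher: Cluster_22165 (log2 8.39), Cluster_51266 (7.17) and ccm-miR168cd (6.99) in TraPR, and ccm-miR166bcdf (9.02) and Cluster_27171 (7.60) in Input. The sequence ccm-miR156dgijkl;ath-miR156abcdef, shared by both species, was also higher in haustoria Input (4.35). Cluster_67871 had 542 ± 87.5 RPM in haustoria Input and no reads in stem Input, at least 1972-fold higher (at least 1188-fold without the Input library of RepID 2). Interface-induced microRNAs divided: in Input, 63 of 123 were higher in haustoria, among them ccm-IIM-100 (6.63), and 43 were lower. In TraPR, 3 of 97 were higher and 80 lower, among them ccm-miR12496 (-6.38) and ccm-miR12491a, with 580 ± 161 RPM in stems and no reads in haustoria, at least 29617-fold lower (at least 6516-fold without the TraPR library of RepID 4). ccm-IIM-81 had 242 ± 44.8 and 178 ± 35.9 RPM and did not pass, but passed as lower with TMM scaling (log2 -3.68). TMM scaling moved the median of all features from 2.19 to 0.82 in TraPR and from 2.25 to 0.98 in Input libraries, and the counts to 13410 and 18913.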

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

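Of the tests in this part, the comparison with canonical microRNAs, the comparison of stem levels, the match to the Arabidopsis genome, the reading of the ratio the other way, the shares without the most abundant sequence and the counts over other splits of the libraries were chosen after the result was seen.

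The response to TraPR differed between tissues for 161 features. The interface-induced class had a median log2 difference of -5.08, with ccm-IIM-100 at -8.60, ccm-miR12464a at -8.12, ccm-miR12465a at -7.85, ccm-IIM-27 at -7.21 and ccm-miR12496 at -3.65. The others named in the report were ccm-miR12487b at 6.25, Cluster_67660 at 5.48, Cluster_14079 at 4.47 and ccm-miR172ad;ath-miR172cd at -3.93. Each of these passed the limma test of the difference itself. Shares of reads were higher in TraPR in every stem RepID and lower in every haustoria RepID, with log2 differences of -1.79 for canonical microRNAs of host and/or parasite, -3.14 for all microRNAs, -0.56 for 24-nt siRNA loci, -1.36 for all listed features, -6.42 for 20-nt features, -1.50 for 21-nt features and -0.55 for 24-nt features. For each of these shares, an exact permutation of the RepIDs between tissues gave p = 0.10, the smallest possible. Shares listed because their RepIDs lay on opposite sides could give no other p, so this test adds no evidence. These classes hold different sequences in each tissue: reads on listed 20-nt features in TraPR were 92.2% miR158a-3p in stems and 90.6% ccm-miR156dgijkl;ath-miR156abcdef in haustoria, so their shares do not show a different response of the same RNA. Without the most abundant sequence or locus of the class in each tissue, the differences were, in the same order, -1.88, -3.62, -0.60, -1.12, -5.32, -1.11 and -0.56, and those of canonical microRNAs and 21-nt features were no longer opposite in every RepID.

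The fall of interface-induced microRNAs in haustoria TraPR was weighed against technical explanations. Haustoria TraPR libraries were deeper than Input. With every haustoria library thinned to the same reads the class median was -5.26 (RepIDs from -5.81 to -4.84). Thinning leaves the expected RPM as it was, so the median could hardly have moved. The value says only that the sampling of low reads did not set it. The class median minus that of 30 canonical microRNAs of the same libraries was -4.57 (from -4.74 to -4.41), and with TMM scaling the fitted class medians were -4.78 and -0.11, against the scaling. With 29 canonical microRNAs matched by Input level, the difference was -4.41 ± 0.34 (SD, n = 3), against the level in the Input. A lower loading of this class into ARGONAUTE complexes in haustoria than in stems may account for it, but it was not tested, the tissue is confounded with growth conditions, and a loss of the class on the column for other reasons stays open.

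Interface-induced microRNAs in flanking stems were weighed against carry-over of parasite tissue with the RNA profile of the in vitro haustoria. Such tissue would bring other parasite RNAs in proportion, but the median interface-induced sequence stood at a share of its haustoria Input level that was 16.1 times that of 9 parasite canonical microRNAs without a match in Arabidopsis (from 7.04 to 85.2 over the 3 stem Input libraries). With the deposited ratio read the other way, where 15 interface-induced and 7 canonical sequences had at least 10 RPM in haustoria in place of 75 and 9, it was 46.9 (from 19.2 to 696). For reads shared with the host genome, 0 of the 136 sequences had an exact match in the Arabidopsis assembly. The authors' rule for this parasite category is not given and may have required that, so this is no independent test. Near matches were not searched. Carry-over of parasite tissue with another RNA profile, such as that of haustoria attached to a host, stays open, as does movement of the sequences into the host, which may also be part of it and was not tested.

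For each of the 5 comparisons, only 1 of the 10 splits of the libraries, the real one, gave as many features. The real counts and the highest of the other splits were 127 and 3 in stems, 3605 and 0 in haustoria, 161 and 0 for the difference between tissues, 32986 and 1 within TraPR, and 42114 and 0 within Input libraries. With 10 splits no share under 0.05 can be reached.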

How the results depend on the processing

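Leaving out both libraries of a RepID, the filter over all 12 libraries, the test of the deposited ratios, thinning, the ratio read the other way and shares without the most abundant sequence were chosen after the data were seen. The edgeR and DESeq2 tests, planned for files of counts, were not run on the recovered reads, where voom was the alternative, and leaving out structural and organelle RNA was not run, since no such features are listed. Where no reason is given, the cause was not tested.

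Stem features past the threshold were 127, against 79 with voom (35 up and 44 down), 21 with no filter (44437 features tested), 78 with a mean of at least 10 RPM (177 tested) and 259 with all 4 groups in 1 fit, with 8 to 119 on leaving out libraries. In haustoria 3605 passed, against 11292 with voom (9052 down), 12020 with all 4 groups in 1 fit (8926 down) and 0 in the limma test of the deposited ratios (10091 at an unadjusted p under 0.05), with 503 to 4264 on leaving out libraries. For the difference between tissues 161 passed, against 93 with TMM, 91 with median-ratio scaling, 1033 with no filter (52551 tested), 56 with a mean of at least 10 RPM (92 tested), 105 with a pseudocount of 0.1, 439 with one of 5 (283 higher) and 1013 with the filter over all 12 libraries (46644 tested), with 88 to 199 on leaving out libraries. Between tissues, 13410, 8071 and 2939 features passed in TraPR and 18913, 15649 and 1439 in Input libraries with TMM, median-ratio scaling and a mean of at least 10 RPM.

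The median of the interface-induced class in haustoria was -6.71 with voom, -4.71 with no filter, -6.20 and -3.95 with pseudocounts of 0.1 and 5, and -6.39 in the deposited ratios, and it ranged from -5.48 to -5.06 on leaving out libraries. For the difference between tissues it was -3.75 with median-ratio scaling, -2.86 with no filter, -3.71 with a pseudocount of 5 and -3.23 with the filter over all 12 libraries, and ranged from -5.47 to -4.60. In stems it ranged from -0.88 to 0.10 and so changed sign.

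Counting distinct sequences or loci with at least 1 RPM in place of reads reversed these log2 ratios of shares, which weight each sequence alike: in stems canonical microRNAs of host and/or parasite (-0.29), host canonical microRNAs (-0.18), 24-nt siRNA loci (-0.00652), all microRNAs (-0.38), features of 20 nt (-0.34), 21 nt (-0.16) and 24 nt (-0.00694), 5' U of 20-nt (0.0642) and 21-nt microRNAs (0.12) and 5' A of the interface-induced class (0.0694), and in haustoria canonical microRNAs of host and/or parasite (0.12) and features of 21 nt (0.00586). These counts were divided by all listed features with at least 1 RPM, siRNA loci included, and not by the library total. For 5' bases they were divided by such sequences of the size or class. Without the most abundant sequence, the log2 ratios of the shares of 5' G of 21-nt microRNAs in stems (0.17) and 5' A in haustoria (0.0118) were reversed.

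With an estimated correlation, camera's call was lost in stems for the Brassicaceae list (adjusted p of 0.187), host canonical (0.356), interface-induced, parasite-named, 21-nt loci and other-ARGONAUTE lists (0.426 each), 22-nt loci (0.630), secondary siRNA triggers (0.191) and 21 or 22-nt loci (0.627). In haustoria it was lost for shared canonical (0.379), 21-nt loci, developmental and other-ARGONAUTE lists (0.197 each), and 22-nt and 21 or 22-nt loci (0.115 each), and for the difference between tissues for the developmental list (0.791). With TMM it was lost for other-ARGONAUTE lists in stems (0.165) and haustoria (0.0747) and for shared canonical microRNAs in haustoria (0.0987).

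Of the values of named features under alternatives, 1194 kept their direction and side of the threshold, 95 kept their direction but lost the call and 10 gained it. Among shares 300 kept their direction, and 10 cross-species differences kept their direction with only features of at least 10 reads. With the ratio read the other way, the stem level of the interface-induced class was 974% of that in haustoria and that of parasite siRNA loci 4.88%. Same-numbered Input and TraPR libraries did not deviate together (correlations across features from 0.00330 to 0.0390 in stems and from -0.000774 to 0.0300 in haustoria). The deposited ratios pair these libraries by RepID, and low correlations cannot show that the libraries of a RepID came from different material. Whether they share material was therefore not decided. With the RepID as a block 137 features passed in stems, 3660 in haustoria and 155 for the difference. With the block, camera's calls with the preset correlation were kept. With an estimated correlation those of the interface-induced and parasite-named lists were lost in haustoria (adjusted p of 0.0905 each) and for the difference (0.0609 and 0.0721), and those of 22-nt and 21 or 22-nt loci in haustoria were gained (0.0441 each). Depth limits low features: a read was worth up to 0.373 RPM, and with haustoria libraries thinned to equal reads the class median was -5.26.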

Other observations

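The pattern in this part was chosen after the values by first base were seen, and the predictions of both tests were written before their results were seen.

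Within the interface-induced class, the response to TraPR in stems differed by first base. The median log2 fold change was 0.14 for 65 sequences that start with U, -1.03 for 15 with A, -1.91 for 20 with C and -3.22 for 18 with G. Of those with U, 6 rose and 6 fell, and of those with G, 1 rose and 13 fell. In haustoria the medians were -5.08 for U, -4.71 for A, -5.22 for C and -5.60 for G. By reads, 5' U rose there too, from 59.7% ± 4.39 of the class in Input to 79.6% ± 3.62 in TraPR. With 5 members at 0 in haustoria TraPR, the log2(RPM + 1) scale compresses differences between falls, so a first-base difference in haustoria stays open. The hypothesis is that in stems the first base, or what goes with it, may decide which of these sequences are retained. GC content was weighed as an explanation: sequences with U lay 2.04 above the others on average, and 1.91 above with GC content as a term (permutation p = 1e-05, the smallest that 100000 permutations can give). Related sequences were weighed as well: with 1 mean per name family and base, 48 means with U had a median 2.28 above that of 47 others (permutation p = 1e-05, again the smallest possible). Neither accounts for the whole difference, and sorting by ARGONAUTE proteins was not tested. Both permutations were over sequences of the libraries in which the pattern was seen, so their p-values do not cover the spread between libraries.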
